A study of Mus musculus with 72 samples.

How the data were processed

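Single-nucleus RNA was read in 40 libraries of micro-dissected mouse cortex, 28 from C57Bl/6 lab mice and 12 from wild-derived mice, in 7 groups of area and strain. Of these, 32 were made with 10x multiome, which reads RNA and open chromatin (ATAC) from the same nuclei, and 8 wild-derived libraries with 10x RNA version 3.1. The libraries were grouped by area and strain as the labels give them, and each library was taken as 1 replicate. The deposited matrices hold counts: whole UMI counts per gene and barcode and, in the multiome libraries, whole ATAC counts per peak and barcode, with no normalization by the authors. The authors' notes name Cell Ranger ARC 2.0.0, Cell Ranger 6.0.0 and the mm10 genome build. For wild-derived pPir the protocol text counts 1 of 4 libraries as v3.1 and the titles 3 of 4. The titles were followed, as the matrices of those 3 hold no ATAC counts. Peaks differed in number and position between the deposited matrices, so they had been called per library. Whether introns were counted was not stated in the labels. The lab mice are of the strain that the mm10 reference represents, and the wild-derived mice are not.

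Barcodes with at least 500 detected genes and under 5% mitochondrial UMIs were kept, 68207 of 82928. Doublets were scored per library with Scrublet in scanpy 1.11.5 (Python 3.11.15), and the top-scoring nuclei were left out at a rate of 0.8% per 1000 barcodes, 4036 nuclei or 5.92%. This fixed rate took the place of the tool's own threshold after that threshold was seen to mark few nuclei in large libraries. Counts were scaled per nucleus and log-transformed, 3000 variable genes were chosen within each chemistry, and nuclei were clustered on 40 principal components and 15 neighbours with the Leiden method at resolution 1.5. The 55 clusters were named from marker lists fixed before the data were examined, by the mean over a list of each gene's level relative to the cluster where it is highest. A class was offered as a name only where some cluster had 2 of its markers among its top 10 genes. A cluster stayed unnamed when at least 50% of its nuclei were scored as doublets, when fewer than 3 markers were detected in 10% of its nuclei, when its median UMI count was under 0.6 of the library median with no marker among its top 10 genes, or when its second-best score exceeded 0.7 of the best. It also stayed unnamed when the top 10 genes held more markers of another class, or, for non-neuronal classes, none of its own. This naming rule was revised once after its first output was seen. Among nuclei of v3.1 libraries, 28.4% in aPir, 21.7% in pPir and 7.52% in SSp fell in unnamed clusters of low UMI count. Sub-clusters of glutamatergic nuclei were named the same way at a marker score of at least 0.5. They served to leave deep-layer types out in an alternative and to give the shares of layer types in the Results.

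Raw counts were summed per library over the glutamatergic and, separately, the GABAergic nuclei, wherever a library held at least 20 nuclei of the class. Sums were compared with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM normalization, quasi-likelihood fits and tests, and Benjamini-Hochberg adjusted p under 0.05 for a call. Every adjusted p given for a gene or region comes from these edgeR fits and every p is two-sided. Lab libraries of the 4 areas shared 1 fit, with piriform cortex as the mean of aPir and pPir. Strain contrasts used all 40 libraries for glutamatergic nuclei and 27 for GABAergic nuclei, with a term for chemistry, so that the strain values rest on the 4 wild-derived multiome libraries and on a chemistry effect shared by the areas. The contrast between classes used 2 sums per library with library as a block, over 10 piriform and 4 SSp libraries. GABAergic sums reached 20 nuclei in 3 aPir, 7 pPir, 1 AI and 4 SSp lab libraries. CPM are counts relative to TMM-scaled library sizes, in edgeR's usual unit. An error given with a mean is the SD over libraries, and SE is that of the fitted log2 fold change.

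For ATAC, the peaks of the lab libraries were merged into 286116 regions for the glutamatergic sums, and a region was used only when every library of the fit had called a peak there, because a library gives no count where it called none. This left 35549 regions holding 56.7% of the counts in glutamatergic nuclei and 48838 of 262178 regions holding 70.7% of those in GABAergic nuclei. Genes were placed with RefSeq coordinates of the same build, which cover 92.7% of the tested symbols. The plan had been to take transcription starts from the matrices' own feature lists, but those give no gene positions. The RefSeq coordinates used carry no strand, so the promoter of a gene was taken as the end of its span with the more accessible region within 1 kb, or within 5 kb as an alternative. That choice used pooled counts of all areas.

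The genes named in the text follow a rule fixed before the data were examined: up to 12 genes each way with the largest change among those past the threshold, with a mean of at least 30 CPM in the higher group, every library of 1 side above every library of the other (multiome libraries for strain), and no predicted-gene symbol, plus the tested members of the gene lists. Some genes that this rule gives are not reported here, though the counts include them. For ATAC the 10 regions each way with the largest change were eligible. The 13 gene lists held layer identity transcription factors, pallial patterning transcription factors, immature neuron genes, immediate early genes, neuropeptides and calcium buffers, potassium and HCN channels, glutamate receptors, GABA-A receptors, neuromodulator receptors, axon guidance genes, cadherins and contactins, antigen presentation genes, and RNA quality genes. Lists were tested in 8 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated, which held 5 of the 22 list calls.

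Shares of a class were taken over nuclei after doublet removal and compared between libraries by two-sided exact permutation tests of the difference in means, within area for the strain contrast. The 36 tests of other classes were Benjamini-Hochberg adjusted. A share of 0 is given with the limit that 3 counts would allow, and intervals and limits cover counting error alone. Separation of glutamatergic nuclei was measured on 50 nuclei of 2000 UMIs per library in 20 draws, as the best mean silhouette of k-means clusterings with k from 2 to 8 on 10 principal components of 1000 variable genes. Correlations across genes used 100000 permutations.

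Total UMIs per library were 3662817 to 16852031 in lab multiome, 12046313 to 27090487 in wild-derived multiome and 24755754 to 49537300 in v3.1 libraries. Tested on simulated counts, drawn from the means, spread and depths of the real fits with changes put into 200 genes or regions, the fits recovered between 36% and 99% of 2-fold changes and between 85% and 100% of 4-fold changes, lowest for ATAC in GABAergic nuclei. Alternatives tried were DESeq2 1.42.0, RLE size factors, no filter on low counts, doublets kept, 1000 genes per nucleus, thinning of all sums to the smallest, leaving out single libraries, the replicate number as a block, leaving out deep-layer sub-clusters, multiome libraries alone, other region rules, and other denominators or settings for the shares and the silhouette. After the data were seen, 3 more were added: single aPir libraries left out where few entered a fit, the share of UMIs at 6 ribosomal protein genes as a covariate, and the lab libraries numbered 1 or 2 left out. The pPir against aPir comparison of immature neuron shares was also added then. No replicate block stands in the fits reported, since the labels do not say whether equal numbers mark 1 animal. ATAC of wild-derived mice was not analysed here.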

Results

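RNA of single nuclei was counted in 4 areas of mouse cortex. These were the anterior piriform cortex (aPir) and posterior piriform cortex (pPir), which are the parts of the primary olfactory cortex, the agranular insular cortex (AI), and the primary somatosensory cortex (SSp), a 6-layered neocortical area. C57Bl/6 lab mice gave 9 aPir, 10 pPir, 5 AI and 4 SSp libraries, all made with 10x multiome, an assay that reads RNA and open chromatin (ATAC) in the same nucleus. Wild-derived mice gave 6 aPir libraries (2 multiome), 4 pPir libraries (1 multiome) and 2 SSp libraries (1 multiome), the remaining 8 being made, by their titles, with the 10x RNA assay v3.1. The values deposited by the authors are whole counts. Of 82928 barcodes 68207 passed the filters, and 64171 nuclei were left after doublet removal. Total UMIs per library were 3662817 to 16852031 in lab multiome, 12046313 to 27090487 in wild-derived multiome and 24755754 to 49537300 in v3.1 libraries. The median nucleus had 9794 to 45340 UMIs in lab libraries and 2426 to 5376 in v3.1 libraries. All positions are in the mm10 build.

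Glutamatergic nuclei made up 57% of nuclei in lab piriform libraries, 56.9% in AI and 62.1% in SSp, and GABAergic nuclei 6.60%, 7.16% and 8.47%. Among lab mice, a cluster led by Epha6, Ndst4 and Rfx3 held 44.5% of glutamatergic nuclei in aPir, 48.8% in pPir and 38.6% in AI. A cluster led by Ntng1, Ankfn1 and Fyb2 held 31.3% in aPir, 21% in pPir and 16.3% in AI. In SSp, 68.7% fell in a cluster led by Pparg, Prr16 and Exph5, which held 10.2% in AI, and 19.7% in a cluster led by Cdh18, Thsd7b and Foxp2. A cluster led by Npsr1, Oprk1 and Nr4a2 held 12.9% in AI and 8.24% in pPir. Of SSp glutamatergic nuclei, 28% ± 9.71 (SD, n = 4) resembled layer 4/5 intratelencephalic neurons by the neocortical marker lists and 18.2% ± 5.93 resembled layer 6 corticothalamic neurons. By the same lists 97.0% ± 3.57 (SD, n = 9) of aPir glutamatergic nuclei took no layer name. Oligodendrocytes were 3.38% ± 1.04 (SD, n = 10) of nuclei in pPir and 8.36% ± 3.91 (SD, n = 9) in aPir (exact permutation p = 8.66e-05, adjusted p = 0.00312 over 36 tests). Oligodendrocyte precursors were 6.49% ± 1.56 in pPir and 4.34% ± 1.25 in aPir (exact permutation p = 0.00152, adjusted p = 0.0273). The remaining 34 tests of class shares between areas did not pass. Few splits exist between 5 AI and 4 SSp libraries, so those tests could hardly reach an adjusted p under 0.05. Oligodendrocytes were 1.34% to 4.29% of nuclei in AI libraries and 6.76% to 13.1% in SSp libraries, without overlap. Their precursors were 5.36% to 9.20% in AI and 2.98% to 4.71% in SSp, so a difference in these shares stays open.

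Immature neurons, a cluster led by Igfbpl1, Sox11, Tfap2d, St8sia2 and Epha3, were found in piriform cortex and not in SSp. The comparison asks whether the olfactory cortex holds neurons that still express genes of neuronal maturation. They were 4.00% ± 3.54 (SD, n = 19) of lab piriform nuclei, 259 of 7084, and 0 of 1684 nuclei in SSp (n = 4), which allows a share of up to 0.178%. The difference passed a two-sided exact permutation test (p = 0.0364, 8855 splits), but leaving out any 1 SSp library ended the call (exact permutation p = 0.0636). In AI they were 0.763% ± 0.879 (SD, n = 5), a difference from piriform that did not pass (exact permutation p = 0.0506) and that passed as a share of neurons (exact permutation p = 0.0398). Within piriform cortex the share was 6.30% ± 3.44 (SD, n = 10) in pPir and 1.44% ± 0.957 (SD, n = 9) in aPir (exact permutation p = 0.000162, a comparison chosen after the shares were seen). In wild-derived multiome libraries the mean over the piriform areas was 1.46%, against 3.87% in lab mice, a difference that did not pass (exact permutation p = 0.117, n = 3 and 19). In v3.1 libraries the share was 0.344% ± 0.152 (SD, n = 4) in aPir and 1.76% ± 0.347 (SD, n = 3) in pPir. With these included the strain difference passed (permutation p = 0.00561, 100000 draws), though v3.1 was used for wild-derived mice alone.

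**Figure D1:**
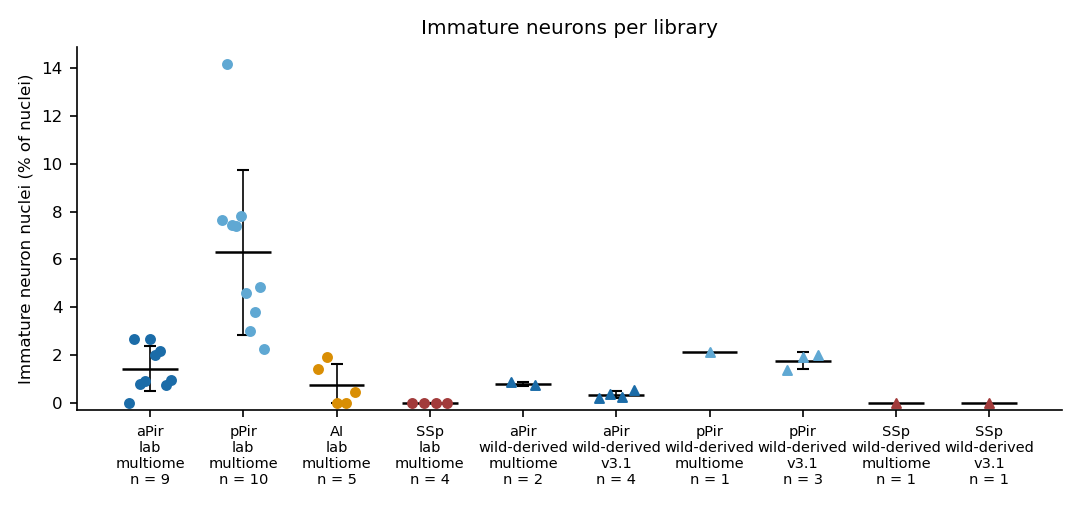
Share of immature neurons in percent of nuclei by area, strain and assay; points are libraries, lines are means and bars are the SD. The 4 SSp lab libraries hold 0 such nuclei, and pPir lab libraries lie above aPir lab libraries on average (6.30% and 1.44%).

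Glutamatergic nuclei of piriform cortex and SSp differed in single genes such as Ndst4, Htr2c and Erbb4 and in lists of layer and pallial transcription factors. The comparison addresses how the neurons of the olfactory cortex differ from those of neocortex. Higher in piriform were Ndst4, which makes heparan sulfate, Htr2c, a serotonin receptor, Erbb4, a neuregulin receptor, and Igf1, a growth factor. The presynaptic gene Unc13c, the transcription factors Dach1 and Npas3, the phosphatase Ptpro, the dehydrogenase Dpyd, and the adhesion and polarity genes Dchs2, Cntnap5c and Pard3b were also higher. Lower in piriform were the transcription factors Foxp2, Barx2 and Zbtb16, the guidance genes Ephb2, Ephb6, Robo3 and Sema3e, and the signalling genes Plcb4, Chn2, Kctd8, Pld5 and Stxbp6. Ndst4 (ENSMUSG00000027971, chromosome 3, 125404029 to 125728351) was at 466.3 ± 155.7 CPM (SD, n = 19) in piriform and 5.75 ± 6.06 CPM (SD, n = 4) in SSp, a log2 fold change of 6.44 (SE 0.67, adjusted p = 2.4e-08). The log2 fold changes of Htr2c, Erbb4 and Dpyd were 5.43, 5.20 and 4.70. Foxp2 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977) was at 11.3 ± 9.80 CPM in piriform and 247 ± 56.4 CPM in SSp, a log2 fold change of −4.50 (SE 0.51, adjusted p = 8.92e-08). Those of Plcb4, Ephb2 and Ephb6 were −3.75, −3.39 and −3.37. In all, 2025 of 14740 genes rose and 1918 fell. As the rule for naming requires, all 19 piriform libraries lay on 1 side of all 4 SSp libraries for every gene named here outside the lists.

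Of 23 neocortical layer identity factors 13 fell and 2 rose in piriform, the same counts as adjusted over the list alone. Fezf2 fell by 3.80 log2 units and Rorb by 2.57, while Bcl6 rose by 2.07 and Bcl11b by 1.59. The list as a whole was lower (camera adjusted p = 2.21e-05). Of 21 pallial patterning factors 10 rose and 4 fell (11 and 5 adjusted over the list alone). Besides Dach1 and Npas3, Tfap2d rose by 3.50 and Meis1 by 2.70, while Emx1 fell by 0.83. The list was higher (camera adjusted p = 0.00231). Neuropeptides and calcium buffers held 5 that fell and none that rose of 15, among them Pvalb with −3.57, Npy with −2.24 and the layer 4 gene Rspo1, at 0.0463 CPM in piriform and 13.6 CPM in SSp. That list was lower (camera adjusted p = 0.0294), a call lost at adjusted p = 0.372 with an estimated correlation. Pvalb was also lower in GABAergic nuclei of piriform cortex, and whether free RNA of those nuclei adds to the glutamatergic values was not tested. Across the 8 comparisons tested, 22 of 104 list tests were called and 5 held with an estimated correlation: layer factors and pallial factors in piriform against SSp and against AI, and pallial factors in pPir against aPir.

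The other lists were not called between piriform and SSp, and most of them held genes that changed in both directions. Of 33 guidance genes 14 rose and 9 fell, Nrp2 by 3.78 up and Robo3 by 3.16 down, and of 26 cadherins and contactins 10 rose and 4 fell (11 and 4 adjusted over the list alone), Cntn5 by 2.59 up and Cdh6 by 2.13 down. Of 27 potassium and HCN channels 7 rose and 9 fell (8 and 9 adjusted over the list alone), with Kcnn3 at 2.50 and Kcnt2 at −1.11. The median of this list was −0.14, its mean 0.05 and its test upward. Of 23 glutamate receptors 6 rose and 9 fell (7 and 9 adjusted over the list alone), with Grin3a at 3.13 and Grm3 at −2.44. Of 12 GABA-A receptors 2 rose and 4 fell (2 and 5 adjusted over the list alone), with Gabrg1 at 2.06 and Gabrg3 at −0.95. Of 28 neuromodulator receptors 4 rose and 9 fell (5 and 9 adjusted over the list alone), Htr2c leading those that rose and Adra1a, at −1.77, among those that fell. The median of this list was −0.12, its mean 0.41 and its test downward. Npy2r was at 2.07 CPM in piriform with no count in SSp. Of 10 antigen presentation genes 3 fell (4 adjusted over the list alone), including H2-T23 by 2.47 and B2m by 2.29. Of 7 immature neuron genes 2 rose and 1 fell, Sox11 by 0.90 up and Nrep by 2.17 down. Of 20 immediate early genes Ier5 and Arc fell, by 2.11 and 1.10. None of 17 RNA quality genes passed. Of the cell type markers, the layer 6 corticothalamic list was lower in piriform, 4 of 8 genes having fallen (camera adjusted p = 0.000724, and 0.0361 with an estimated correlation).

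**Figure D2:**
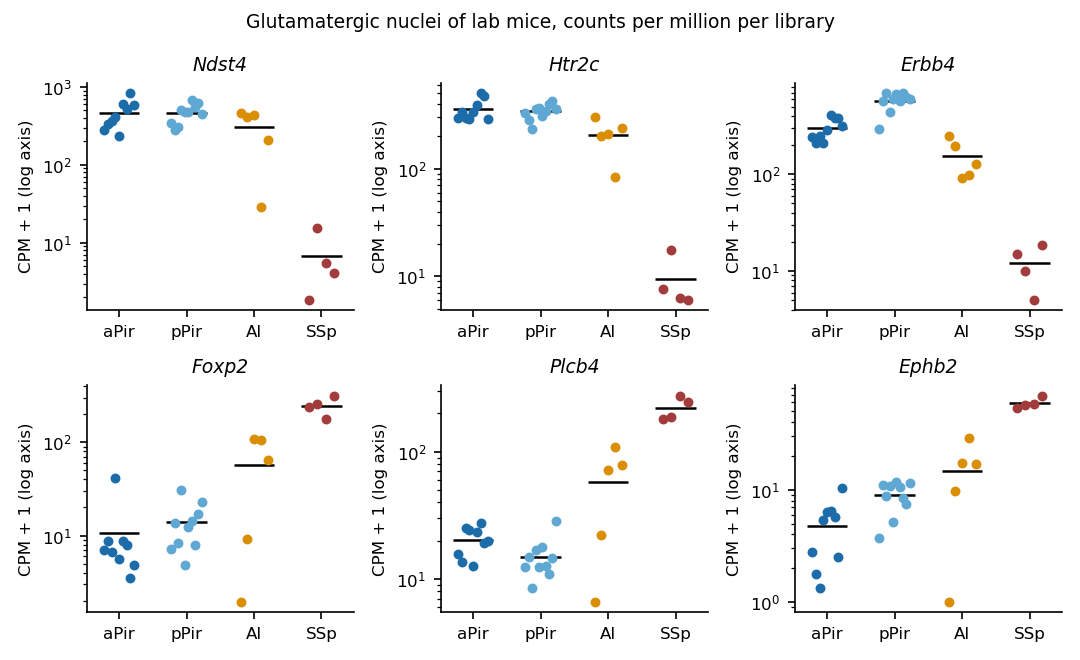
CPM plus 1 on a log axis in glutamatergic nuclei of lab mice, for leading genes of piriform against SSp; each point is 1 library and lines are means. Ndst4 averages 466.3 CPM in piriform libraries and 5.75 CPM in SSp libraries.

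Glutamatergic nuclei of piriform cortex and AI differed in the lists of layer and pallial transcription factors. AI lies next to the piriform cortex and is a transitional area, so the comparison asks which differences from SSp it shares. Dach1 was at 113 ± 31.5 CPM (SD, n = 19) in piriform and 22.9 ± 7.85 CPM (SD, n = 5) in AI, a log2 fold change of 2.28 (adjusted p = 1.31e-06), and Tshz3 was higher by 0.55 (adjusted p = 0.00344). These 2 genes alone met the rule for naming, which asks for at least 30 CPM and no overlap between the libraries of the 2 sides. Of the 23 layer factors 4 fell in piriform (7 adjusted over the list alone), among them Fezf2 by 3.46, Foxp2 by 2.38 and Tox by 0.99 (camera adjusted p = 0.000776). Foxp2 turned direction, to 0.88, when deep-layer clusters were left out. Of 21 pallial factors 5 rose and 1 fell (8 and 2 adjusted over the list alone), with Npas3 at 1.52 and Lhx2 at 1.08 (camera adjusted p = 1.18e-05). Of 28 neuromodulator receptors 4 fell and 1 rose (5 and 2 adjusted over the list alone), including the opioid receptor Oprk1 at −2.46 and Adra1a at −1.96 (camera adjusted p = 0.000262), a call lost at adjusted p = 0.121 with an estimated correlation. No potassium or HCN channel passed (1 rose adjusted over the list alone), though the list was called higher (camera adjusted p = 0.0205, and 0.528 with an estimated correlation). In all 120 genes rose and 219 fell. This count depended on libraries and settings. It became 995 without AI 1, 73 without AI 6, 99 without AI 7 and 137 without AI 5, and 2264 without the lab libraries numbered 1 or 2, 910 with the ribosomal share as a covariate, 579 with DESeq2 and 180 with all sums thinned. It was 161 with the replicate number as a block, where 12 of the 23 genes named by the rule or the lists lost their call.

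**Figure D3:**
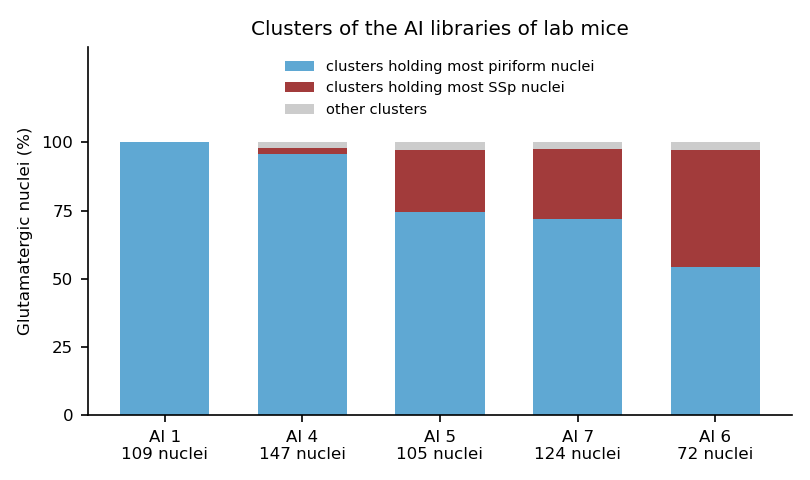
Glutamatergic nuclei of each AI lab library in percent, stacked by clusters that hold most piriform nuclei, most SSp nuclei, or neither. AI 1 has 100% in the piriform clusters and AI 6 has 54.2%. The piriform clusters include the one led by Npsr1, Oprk1 and Nr4a2, which held a larger share of AI than of pPir.

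AI was compared with the same 4 SSp libraries as piriform, so genes called in both comparisons share that side. In the AI libraries 54.2% to 100% of glutamatergic nuclei fell in clusters that hold most piriform nuclei. These include the cluster led by Npsr1, Oprk1 and Nr4a2, which held more of AI (12.9%) than of pPir (8.24%). The shares thus do not count nuclei particular to piriform cortex. Whether piriform tissue in the dissections contributes to the genes below was not tested. Higher in AI were Ndst4, Htr2c, Dpyd, Erbb4 and Ptpro, with the glutamate receptor gene Grin3a, the angiopoietin gene Angpt1, the semaphorin receptor Nrp2, the calcium-binding Cpne7, the apoptosis gene Hrk, the sulfotransferase Chst9 and Cntnap5c. Lower were Chn2, Kctd8, Barx2, Robo3, Pld5, the factors Satb1 and Rorb, Rell1, the peroxisomal transporter Abcd2, Astn2 and Lynx1. Ndst4 was at 306 ± 185 CPM (SD, n = 5) in AI, a log2 fold change of 5.83 (SE 0.68, adjusted p = 5.75e-07). Chn2 was at 4.50 ± 1.15 CPM in AI and 51.6 ± 12.7 CPM in SSp, a log2 fold change of −3.54 (adjusted p = 1.05e-07). Those of Htr2c, Grin3a, Satb1 and Rorb were 4.68, 4.01, −2.66 and −2.51. In all 1152 genes rose and 973 fell, a total of 2125 that was 3559 with the ribosomal share as a covariate. Markers of another cell type moved with them, as 4 of 8 striatal medium spiny neuron genes rose and none fell (camera adjusted p = 0.0252, and 0.0549 with an estimated correlation). Of 23 layer factors 7 fell and 2 rose (8 and 3 adjusted over the list alone), a call (camera adjusted p = 0.0364) lost at adjusted p = 0.159 with an estimated correlation.

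Posterior and anterior piriform glutamatergic nuclei differed in pallial patterning factors and in single genes such as Calb1 and Abi3bp. Higher in pPir were the calcium buffer Calb1, the phosphatases Ptprz1 and Ptpn14, the vesicle gene Otof, Hap1, the transcription factors Lhx2 and Npas3, Ttc28, the phosphodiesterase Pde3a, Pfkfb4, the channel Trpm3 and Dsel. Lower were the matrix gene Abi3bp, Adarb2, Fyb2, Mctp2, Golim4, Arhgap24, the netrin-related Ntng1, the zinc finger genes Zmat4 and Zfp536, Nell1, Lhfp and the repressor Bcl6. Calb1 was at 46.1 ± 13.1 CPM (SD, n = 10) in pPir and 10.0 ± 6.16 CPM (SD, n = 9) in aPir, a log2 fold change of 2.16 (adjusted p = 0.000248). Abi3bp was at 40.6 ± 16.9 CPM and 232 ± 86.7 CPM (log2 fold change −2.52, adjusted p = 0.000126). Ptprz1, Otof, Adarb2 and Fyb2 changed by 1.76, 1.61, −2.08 and −1.98. In all 608 genes rose and 693 fell, a total of 1301 that was 2161 with the ribosomal share as a covariate. Of 21 pallial factors 4 rose and 2 fell (6 and 2 adjusted over the list alone), with Nr2f2 at 2.76, Lhx2 at 1.40 and Emx2 at −1.49 (camera adjusted p = 0.00361). Marker lists of layer 4/5 intratelencephalic and layer 5 extratelencephalic neurons were lower in pPir at the preset correlation alone. Ntng1 and Fyb2, both lower in pPir, were among the leading genes of a cluster that held 31.3% of aPir and 21% of pPir glutamatergic nuclei. Abi3bp and Cdh9 were among those of a cluster that held 10.3% and 7.64%, though Cdh9 was higher in pPir. Whether the mix of neuron types differs, or accounts for these gene changes, was not tested.

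Lists of receptor, adhesion and channel genes were called along piriform cortex at the preset correlation alone. Of 23 glutamate receptors 4 rose and 1 fell in pPir (6 and 1 adjusted over the list alone), including Grin2d at 0.79 (camera adjusted p = 0.000398). Of 12 GABA-A receptors 4 rose and 2 fell (5 and 2 adjusted over the list alone), including Gabra5 at 0.78 and Gabra2 at 0.74 (camera adjusted p = 0.0118). Of 26 cadherins and contactins 9 rose and 3 fell, including Cdh13 at 1.78 and Cdh9 at 1.17 (camera adjusted p = 0.00459). Of 27 potassium and HCN channels 6 fell and none rose (10 and 2 adjusted over the list alone), including Kcnh5 at −1.0 and Kcna2 at −0.88 (camera adjusted p = 0.0118). Each of these 4 calls was lost at adjusted p = 0.481 with an estimated correlation. Of 20 immediate early genes Ier5 fell, by 1.58, and the list was called lower (camera adjusted p = 0.0065, and 0.57 with an estimated correlation). Of 10 antigen presentation genes 2 fell (3 adjusted over the list alone), H2-D1 by 1.43 (camera adjusted p = 0.00608, and 0.236 with an estimated correlation).

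GABAergic nuclei of piriform cortex and SSp differed in single genes such as Htr2c and Pvalb, while no list call held with an estimated correlation. Higher in piriform were the glycine receptor Glra3, Htr2c, Nrp2, Pde3a, the potassium channel Kcnk13, Greb1l, Sntg2, Myof, the proteoglycan Vcan, the GABA receptor Gabrg1, the factor Ets1 and the ephrin Efnb2. Lower were the channel-like Ano3, the calcium buffer Pvalb, Tshz3, the GABA receptor Gabrd, Unc13c, Eya4, the synaptotagmin Syt2, the kinase Prkg2, Ly6e, Npnt, Rgs6 and Frmd6. Htr2c was at 682 ± 142 CPM (SD, n = 10) in piriform and 57.3 ± 55.3 CPM (SD, n = 4) in SSp, a log2 fold change of 3.48 (adjusted p = 1.27e-06). Pvalb was at 13.6 ± 9.93 CPM and 118 ± 48.6 CPM (log2 fold change −3.04, adjusted p = 1.27e-06). In all 421 of 11111 genes rose and 449 fell. The count became 1444 without aPir 0 and 512 without SSp 1, 1336 with no filter on low counts, 480 with all sums thinned, and 460 with the share of UMIs at 6 ribosomal protein genes, such as Rps27, as a covariate, 337 of them called before in the same direction. It was 377 with the replicate number as a block, where 12 of the 61 genes named by the rule or the lists lost their call.

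Of 31 guidance genes in GABAergic nuclei 13 rose and 3 fell (15 and 5 adjusted over the list alone), with Nrp2 at 3.2, Efnb2 at 2.13, Slit1 at 2.12 and Epha4 at −1.96 (camera adjusted p = 7.41e-07, and 0.105 with an estimated correlation). Of 15 neuropeptides and calcium buffers 5 fell and 2 rose (7 and 2 adjusted over the list alone), with Pdyn at −3.64, Crh at −3.58 and Calb1 at 1.79 (camera adjusted p = 0.00324, and 0.209 with an estimated correlation). Of 11 immediate early genes 2 rose (5 adjusted over the list alone), Nr4a3 by 1.61 and Homer1 by 1.05 (camera adjusted p = 0.0149, and 0.209 with an estimated correlation). Of 17 RNA quality genes 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Rps27 at −1.43 and Meg3 at 0.50. The markers of Pvalb interneurons were lower as a list (camera adjusted p = 4.48e-05, and 0.0626 with an estimated correlation).

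Some area differences were not the same in glutamatergic and GABAergic nuclei. The comparison of classes, over 10 piriform and 4 SSp libraries, asks which piriform differences belong to glutamatergic rather than GABAergic nuclei. The change between areas was more positive in glutamatergic nuclei for Unc13c, Dach1, Ptpn14, Ndst4, Erbb4, Npas3, Filip1, Fndc1, Igf1, Dpyd, Tox3 and Grin3a. It was more negative for Nxph2, Pld5, Chn2, Herc6, Plcb4, Kctd8, Stxbp6, Atp8b1, Hcrtr2, Bmper and Rims3. Unc13c was at 371 CPM in piriform (n = 10) and 15.6 CPM in SSp (n = 4) in glutamatergic nuclei, and at 31.7 and 180 CPM in GABAergic nuclei, a difference of log2 fold changes of 6.94 (adjusted p = 2.39e-11). Erbb4, also a marker of GABAergic neurons, was at 11980 and 7635 CPM in GABAergic nuclei. In all 677 genes had a more positive and 624 a more negative change, a total of 1301 that was 586 with all sums thinned to the smallest.

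Wild-derived and lab mice differed in piriform glutamatergic nuclei, a comparison that asks which features of the lab strain hold in mice of wild origin. Reads of both strains were mapped to mm10, which represents the lab strain. Higher in wild-derived mice were Catspere1, a gene of the sperm calcium channel, Phldb2, the collagen-modifying Colgalt2, the junction gene Pkp2, the cilium gene Cfap54, Ccdc3, Plpp4, Sh2d4b, Pdzd2, Iqgap2, Nhs and the kinesin Kif26b. Lower were the keratin Krt12, the ribosomal Rpl29, the phosphatase Acp1, the exchange factor Vav3, Zfp933, the respiratory Sdhb, Cntnap5c, Nsun7, Mpp7, Nvl, the splicing gene Rnps1 and Ulk4. Catspere1 (ENSMUSG00000102483, chromosome 1, 177808419 to 177962253) was at 65.9 ± 10.3 CPM (SD, n = 3) in wild-derived multiome and 1.07 ± 0.815 CPM (SD, n = 19) in lab libraries, a log2 fold change of 6.11 (SE 0.22, adjusted p = 6.93e-22). Krt12 was at 3.65 ± 0.945 CPM and 43.1 ± 17.6 CPM (log2 fold change −3.55, adjusted p = 1.04e-08). In all 1804 of 17191 genes rose and 1315 fell. The total was 1797 with all sums thinned, 1673 with multiome libraries alone and 1462 without pPir 1W. No gene list was called, the lowest adjusted p being 0.484. In glutamatergic nuclei the share of counts at 6 ribosomal protein genes was 0.0164% ± 0.00219 (SD, n = 3) in wild-derived multiome and 0.0344% ± 0.0348 (SD, n = 19) in lab piriform libraries, a difference that did not pass (exact permutation p = 0.42, adjusted p = 0.968 over 5 tests). In lab aPir and pPir 1 and 2 it was 0.0735% to 0.113%, against 0.00634% to 0.0503% in the other 15.

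In SSp, where wild-derived mice gave 1 multiome library and so no spread of their own in that assay, Catspere1 was higher by 5.94 and Krt12 lower by 3.98. Also higher were the stress-response gene Fkbp5, Colgalt2, Cfap54, Bcar3, Dpf3, Tcerg1l, Crispld1, Socs6, Ccdc3, Phactr2 and Zfhx4, and lower were Nrep, Hjurp, Lama4, Sytl2, Nvl, Ulk4, Siae, Ints7, Rnps1, Cyp51 and Trmt6. Fkbp5 was at 90.1 CPM in the wild-derived library and 11.7 ± 2.67 CPM (SD, n = 4) in lab libraries, a log2 fold change of 2.56 (adjusted p = 0.000177). In all 410 genes rose and 333 fell, a total that was 1305 with the ribosomal share as a covariate, 377 with multiome libraries alone, 356 with all sums thinned and 149 without SSp 2W. Of the 32 genes named by the rule or the lists, 9 kept their call without SSp 2W, Catspere1 and Krt12 among them, 22 lost it, Fkbp5 among them, and 1 reversed. No gene list was called. The strain difference itself differed between piriform and SSp for 18 genes upward and 21 downward, none of which met the rule for naming. Among list members Npy2r passed (adjusted p = 0.0185), with 2.21 CPM in the SSp 2W library and no count in lab SSp. Its call was lost in 8 of 23 other settings, among them multiome libraries alone and each of SSp 2W and 6W left out. The count of 39 genes became 75 with DESeq2, 70 with the ribosomal share as a covariate, 7 with all sums thinned, 6 without SSp 2W and 3 with multiome libraries alone.

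In piriform GABAergic nuclei, wild-derived mice again had more Catspere1, Phldb2 and Cfap54. Also higher were Angpt1, the fibrillin Fbn2, Ccbe1, Socs6, Catspere2, Zfp951, Arhgap18, the sorting receptor Sorcs1 and Nsrp1. Lower were Hjurp, Tent5a, Crispld1, the mitochondrial mt-Nd3, Nsun7, Sytl2, Efcab2, Fggy, the potassium channel subunit Kcns3, Tatdn3 and Zfp933. Catspere1 was at 43.6 ± 7.31 CPM (SD, n = 3) against 0.917 ± 1.53 CPM (SD, n = 10), a log2 fold change of 5.54 (adjusted p = 9.22e-12), and Hjurp changed by −2.54 (adjusted p = 6.22e-07). In all 436 of 13121 genes rose and 250 fell, in total 1056 with no filter on low counts, 225 with multiome libraries alone, 143 with all sums thinned and 275 without pPir 1W. Glutamate receptors (3 of 22 rose), neuromodulator receptors (2 of 26, Htr4 and Adra1b, each by 1.40) and guidance genes (3 of 32, Nrp1 by 1.76) were each called higher (camera adjusted p = 0.00806), calls lost at adjusted p = 0.434, 0.14 and 0.434 with an estimated correlation. The markers of Vip interneurons were higher too (camera adjusted p = 0.0205, and 0.41 with an estimated correlation), Vip by 1.90, so a different mix of interneuron types stays open for these lists. Of 17 RNA quality genes mt-Atp6 and mt-Co1 fell, by 1.15 and 1.03 (7 fell and 1 rose adjusted over the list alone), and the list was lower (camera adjusted p = 0.00887, and 0.434 with an estimated correlation).

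Chromatin of glutamatergic nuclei differed between piriform cortex and SSp. Among the regions named here, the largest fold change towards piriform was in Fam178b (chromosome 1, 36594707 to 36596807), at 17.2 ± 3.49 CPM (SD, n = 19) and 0.515 ± 0.308 CPM in SSp (SD, n = 4), a log2 fold change of 5.02 (adjusted p = 4.99e-12). Regions in Bmper and Msi2 were more open by 4.07 and 3.47, and regions 47291 bp from Cspg4b and 40301 bp from Haao by 4.01 and 3.71. Less open were a region 337547 bp from the potassium channel gene Kcnv1 (chromosome 15, 45453459 to 45454520), by 3.92, and regions in Crispld2, Nfix and Grm3 by 2.70, 2.65 and 2.62. RNA of Grm3 was also lower. Of 35534 regions tested, all called in every library, 7003 were more and 6698 less open. With regions called in every library of 1 area 32086 of 102380 differed. Under this rule a library that called no peak entered as having no reads, so missing values can add to the count. In GABAergic nuclei 92 of 43869 regions were more and 93 less open, in total 185. This total became 65 without SSp 6, 67 without SSp 7 and 79 without SSp 1. It was 55 with all sums thinned, 288 with DESeq2 and 2 with the replicate number as a block. With regions called in every library of 1 area it was 4862, where missing peaks again entered as no reads. A region 24234 bp from Adat2 was less open by 4.92 (adjusted p = 0.000375), as were regions in Pde4dip, Fat3 and Epha4 by 3.80, 3.44 and 2.60. A region in Ankrd6 was more open by 3.4, and a region 11412 bp from Zp2 was at 5.65 CPM in piriform and 0 in SSp.

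Promoter accessibility and RNA changed together across genes. Over 10820 genes the Spearman correlation of the 2 log2 fold changes was 0.298 (permutation p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates. It was 0.595 over the 2576 genes called for RNA, a set chosen by the RNA change itself, so the rise adds no support. Of 782 genes called in both, 701 changed in the same direction.

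**Figure D4:**
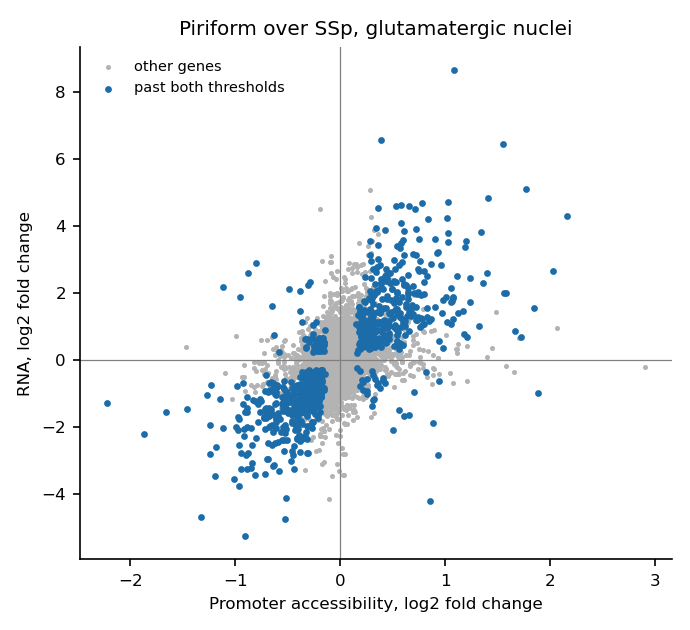
Log2 fold change of RNA (vertical axis) against that of promoter accessibility (horizontal axis), piriform over SSp, in glutamatergic nuclei; each point is a gene, in blue where both passed the threshold. The Spearman correlation over 10820 genes is 0.298.

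No difference in the separation of glutamatergic nuclei into clusters passed between piriform cortex and SSp at the main setting. The best mean silhouette at equal numbers of nuclei and UMIs was 0.275 ± 0.0248 in piriform and 0.279 ± 0.0111 in SSp (exact permutation p = 0.708, SD over libraries). In AI, where nuclei of the Ndst4 and Ntng1 clusters and of the SSp clusters occur together, it was 0.321 ± 0.0426 (exact permutation p = 0.00485 against piriform), a difference that did not pass at 1000 UMIs (exact permutation p = 0.089), with 20 principal components (exact permutation p = 0.848) or without deep-layer clusters (exact permutation p = 0.0707). Without deep-layer clusters, such as those with Foxp2, the value of SSp fell below that of piriform by 0.0356 (exact permutation p = 0.00971). At the main setting the best k, averaged over draws, was 5.7 to 6.8 in SSp libraries and 2.1 to 6.95 in piriform libraries. The silhouettes thus compare unlike numbers of clusters and do not show a like degree of separation.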

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

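The tests of low depth in AI 1, of the v3.1 assay, of the genes higher in wild-derived mice and of the ribosomal share, and the splits with the ribosomal share as a term or within replicate numbers, were chosen only after the results were seen.

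Of 220 values tested, 27 came from a library that lay far from the rest of its group, by the gap to its nearest neighbour relative to the range of the group. Chance gives about 1 in 20 for independent values with a normal distribution. Shares of 1 library and values near 0 need not meet this, so the 27 are not read as an excess. Among class shares of nuclei, aPir lab 0 had 72.4% glutamatergic nuclei and 1.18% oligodendrocyte precursors, and pPir lab 2 had 14.2% immature neurons and 3.33% microglia. Astrocytes were 16.4% in aPir lab 9 and microglia 4.43% in aPir wild 6W. Mural cells were 1.87% in aPir lab 10. They were also 0.775% in AI lab 4 and 0.219% in SSp lab 1, but these are 2 nuclei and 1 nucleus where the other libraries had 0, so any single nucleus would be marked and nothing follows. Fibroblasts were 9.05% in AI lab 1, 3.69% in SSp lab 6 and 4.06% in aPir wild 3W.

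In glutamatergic nuclei, Foxp2 was at 40.7 CPM in aPir lab 3, where the other aPir lab libraries had 2.54 to 7.83 CPM. Barx2 was at 19.0 CPM in pPir lab 5, Kctd8 at 18.8 CPM in aPir lab 9, Plcb4 at 27.7 CPM and Fkbp5 at 66.4 CPM in pPir lab 11, and Colgalt2 at 19.1 CPM in aPir lab 11. In SSp lab 4, Htr2c was at 16.4 CPM, Nrep at 32.2 CPM and Catspere1 at 1.25 CPM, and pPir lab 4 had 3.71 CPM of Catspere1. Tshz3 was at 113.8 CPM in AI lab 1 and Hjurp at 3.74 CPM in aPir wild 3W. In GABAergic nuclei, Htr2c was at 139.8 CPM in SSp lab 7, Nrp2 at 173.1 CPM in pPir lab 9 and Catspere1 at 4.73 CPM in pPir lab 6.

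Effects that differed between groups were marked too. The difference between piriform cortex and SSp itself differed between glutamatergic and GABAergic nuclei for 1301 genes, led by Unc13c and Nxph2. The difference between strains differed between piriform cortex and SSp for 39 genes, Npy2r among them.

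Leaving out AI lab 1 raised the count of genes between piriform cortex and AI from 339 to 995. Low depth argues poorly for this, since with every library thinned to the smallest sum the count still rose 3.81 times, from 180 to 686. At the genes called without it, AI lab 1 lay at a median of 1.29 (quartiles 0.843 and 1.77) on a scale from the other AI libraries at 0 to piriform at 1, while the other 4, measured the same way, lay at −0.53 to 0.595. Its glutamatergic nuclei all fell in piriform clusters, which separates it little, since the other 4 had 54.2% to 95.9% there. Piriform tissue in this dissection is a candidate explanation, and a difference between animals stays open as untested.

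Wild-derived and lab mice differed at 3119 genes in piriform glutamatergic nuclei, led by Catspere1 and Krt12. The v3.1 assay is argued against by 1673 genes called with no v3.1 library, and the ribosomal share by log2 changes that kept 0.974 of their size with it as a term. Reads lost against the mm10 reference cannot be told apart from a change in expression, since such loss would act alike in both classes and GABAergic changes lay between the bounds set at 0.5 and 0.8 of the glutamatergic ones. The median was 0.607 (95% interval 0.562 to 0.665) for genes lower in wild-derived mice, such as Krt12, and 0.562 (95% interval 0.526 to 0.599) for genes higher, such as Phldb2, which loss elsewhere could raise through scaling. A genetic difference in expression between the strains stays open as untested.

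GABAergic nuclei of piriform cortex and SSp differed at 870 genes, led by Glra3, Htr2c, Ano3 and Pvalb. Free RNA of glutamatergic nuclei is argued against, as 99.9% of 835 called genes differed by more than the level it predicts. With the ribosomal share as a term the changes kept a median of 0.844 of their size (quartiles 0.588 and 1.09). In GABAergic nuclei that share was 0.0233% to 0.0828% in SSp libraries. In piriform it was 0.077% in aPir lab 0 and 0.0101% to 0.0195% in the others. Share and area thus went largely together, so the term can hardly separate them and the share stays open as a cause. Calls fell to 460, of which 337 were shared. The median change went from 1.11 to 0.841 and its SE from 0.243 to 0.269. The single genes whose calls ended stay open, as does a different mix of interneuron types.

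Other splits of the same libraries into groups of the same sizes were fitted alike. Chance can be excluded for glutamatergic piriform against SSp (1 of 100 splits, 3943 genes against 3779 for the highest other) and GABAergic strain differences (1 of 60, 686 against 153). The same holds for accessibility in glutamatergic (1 of 50, 13701 against 0 regions called by edgeR) and GABAergic nuclei (1 of 50, 185 against 165). For the difference between classes 21 splits were fitted, and the real one alone called as many (1 of 21, 1301 against 33). So few splits can give no share well under 0.05, so chance is not excluded there. Chance can also be excluded for GABAergic piriform against SSp, where 2 of 100 splits called as many (870 against 891). The highest other splits of that comparison, of glutamatergic piriform against SSp and of GABAergic accessibility kept the 4 SSp libraries together and mixed aPir with pPir alone.

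Some splits point to a structure of the samples. In piriform against AI 3 of 100 splits called as many as the real 339. Of the other splits, aPir lab 1 and 2 with pPir lab 1 and 2 and AI lab 6 against the rest called 4921 genes. Another split that mixed areas called 3333. Groupings that cut across the areas thus called far more genes than the areas did, so these splits do not exclude chance for the 339. In pPir against aPir 3 of 100 called as many (1301 against 1589). In the strain comparison of piriform glutamatergic nuclei 2 of 36 called as many, so chance cannot be excluded: the real split called 3119 genes and aPir lab 1 and 2 with pPir lab 2 called 4530. Those libraries have the highest share of ribosomal protein transcripts. With that share as a term 1 of 36 splits called as many, 4563 genes against 2183 for a split that holds 2 of the 3 wild-derived libraries. The term was chosen after the results were seen, and the share is highest in the libraries of the split that called 4530. This result therefore does not exclude chance for the 3119 genes.

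For glutamatergic RNA of lab mice, areas were also swapped only between libraries with the same replicate number. Chance can be excluded for piriform against SSp (1 of 100 splits, 3943 genes against 3829 for the highest other) and pPir against aPir (1 of 100, 1301 against 1081). For piriform against AI 4 of 100 called as many (339 against 425), a share too near 0.05 for 100 splits to exclude chance. The other splits of piriform against AI that called as many exchanged AI lab 1, and in 2 of them also AI lab 4, with pPir libraries. For AI against SSp, 1 of 100 free splits called as many as the real 2125 genes, the highest other calling 1248. Within replicate numbers 16 splits exist, too few for a share under 0.05, and the real one (1 of 16) called 2125 genes against 855 for the highest other.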

How the results depend on the processing

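The ribosomal share as a covariate, the fits without lab libraries numbered 1 or 2, and those without single aPir libraries were chosen after seeing the data. Depth limits the fits of few nuclei, and for the changes in counts given here the cause was not tested, except that thinning and leaving out libraries leave fewer counts or samples. Thinned to the smallest sum, calls numbered 143 for GABAergic strain differences, 1797 and 356 for glutamatergic strain differences in piriform and SSp, 7 for their difference, 586 for the difference between classes, 480 for GABAergic and 180 for piriform against AI, and 55 for accessibility in GABAergic nuclei. Without a filter on low counts, which tests more genes, 1056 genes differed by strain and 1336 by area in GABAergic nuclei. With multiome libraries only, strain calls were 225 in GABAergic nuclei, 1673 in piriform, 377 in SSp and 3 for their difference. DESeq2 called 75 genes for the difference of strain effects, 579 for piriform against AI and 288 regions in GABAergic nuclei. Regions called in every library of 1 area gave 4862 in GABAergic and 32086 in glutamatergic nuclei. There a peak that a library did not call was entered as no reads, so missing values can add to both counts. With the ribosomal share as a covariate, calls were 1305 for strain in SSp, 70 for the difference of strain effects, 460 for GABAergic piriform against SSp, 910 for piriform against AI, 3559 for AI against SSp and 2161 for pPir against aPir. Without the lab libraries numbered 1 or 2, piriform against AI gave 2264. With single libraries left out, a lone remaining sample being taken to vary like the other groups, counts ranged from 275 (without pPir 1W) to 683 for GABAergic strain differences, from 1462 (without pPir 1W) to 2960 for glutamatergic ones in piriform and from 149 (without SSp 2W) to 693 in SSp. For the difference of strain effects they ranged from 6 to 37, with 6 without SSp 2W, 10 without SSp 6W, 19 without SSp 6, 23 without pPir 1W and 24 without SSp 1. They ranged from 65 to 166 for accessibility in GABAergic nuclei, with 79 without SSp 1, 65 without SSp 6 and 67 without SSp 7. They ranged from 512 (without SSp 1) to 1444 (without aPir 0) for GABAergic piriform against SSp, and from 73 (without AI 6) to 995 (without AI 1) for piriform against AI, with 137 without AI 5 and 99 without AI 7.

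With the replicate number as a replicate block, calls were 4479 for piriform against SSp, 161 for piriform against AI (118 of them among the 339), 3542 for AI against SSp, 1246 for pPir against aPir, 377 for GABAergic piriform against SSp, 35 for the difference of strain effects, and 12616 and 2 regions for accessibility in glutamatergic and GABAergic nuclei. Over 26 pairs of glutamatergic libraries with the same number the median correlation of residuals was 0.318 (lowest 0.0208, with 22 over 0.1), against −0.0548 for other pairs, and 14 of 25 libraries were closest to their own number. The medians were 0.0973 for GABAergic RNA (5 pairs), 0.0664 for glutamatergic accessibility (26 pairs) and 0.00513 for GABAergic accessibility (5 pairs). In glutamatergic RNA, libraries with the same number thus resembled each other more than other pairs did. The fits without a block take such libraries as independent. Since not every pair exceeded 0.1, the block was kept as an alternative only. Whether equal numbers mark a shared animal or batch stays open.

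Leaving out any 1 SSp library kept the difference in immature neurons at 4.00 points and ended its call (exact permutation p = 0.0636). Against AI it passed at 3.32 points with 1000 genes per nucleus (exact permutation p = 0.0461) and at 4.43 points as a share of neurons. The strain difference passed at −2.69 points with all libraries (permutation p = 0.00561, 100000 draws). With single libraries left out it ranged from −2.74 to −2.3751, passing at −2.74 to −2.61 where a pPir library was left out and v3.1 libraries entered, and not passing without aPir 1W or 2W. The separation of piriform minus SSp nuclei reversed to 0.0356 without deep-layer clusters and changed sign without passing at 1000 UMIs (0.014), 30 nuclei (0.0113) and 20 principal components (0.0135), and that of piriform minus AI weakened to −0.0215 at 1000 UMIs, −0.0026 with 20 principal components and −0.0248 without deep-layer clusters. With an estimated correlation 5 of 22 list calls held.

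Among named genes, each tried in several settings, the direction and the call held in 844 of 852 cases for piriform against SSp, 280 of 339 for piriform against AI, 1090 of 1151 for AI against SSp, 559 of 578 for pPir against aPir and 735 of 763 for the difference between classes. They held in 840 of 911 for GABAergic piriform against SSp, 772 of 847 for strain in piriform, 437 of 512 for strain in SSp, 15 of 23 for the difference of strain effects and 664 of 731 for GABAergic strain differences. The others weakened, apart from 2 that reversed. These were Foxp2, glutamatergic nuclei, piriform versus AI, lab mice, at 0.883 without deep-layer clusters, and Htr4, glutamatergic nuclei, wild-derived versus lab, SSp, at −0.001176 without SSp 2W against 2.479 without SSp 6W.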

Other observations

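In pPir against aPir, the layer 4/5 intratelencephalic list was lower (camera adjusted p = 0.000535, and 0.114 with an estimated correlation), as was the layer 5 extratelencephalic list (camera adjusted p = 0.00316, and 0.0508 with an estimated correlation). In GABAergic nuclei of piriform cortex Foxp2 was higher in wild-derived than in lab mice by a log2 fold change of 3.65. Foxp2 was lower in GABAergic nuclei of piriform cortex than of SSp, with a log2 fold change of −4.97.

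Within lab piriform libraries, the first principal component of glutamatergic expression, with the area means removed, held 71.6% of the variance and the next 6.07%. Which genes led it was not examined. The libraries aPir and pPir lab 1 and 2 had the highest ribosomal share, and whether the component follows that share was not tested. In GABAergic nuclei, measured like the glutamatergic ones, the silhouette was 0.279 to 0.382 in 5 libraries.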
